A study of Mus musculus with 5 samples.

How the data were processed

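Wild-type mouse embryonic fibroblasts in 5 libraries were analysed: a control at 0 h, amino acid starvation for 3 h and 6 h, and glucose starvation for 6 h and 12 h, with 1 library per condition. Per the labels' protocols, 500000 cells were plated, the starved cells were washed and given starvation medium with dialyzed serum, and the cells were trypsinized and frozen, the control in complete and the starved cells in dialyzed serum. Per the labels, 5000 cells of each sample were used, and libraries were made with Single Cell 3' v2 chemistry of the 10X kit and sequenced on a HiSeq 4000. The submitters' processing notes name Cell Ranger and the mm10 assembly; the version of Cell Ranger and the gene annotation are not given in the sources used here.

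The deposited table holds raw UMI counts, 1 column per cell barcode and 1 line per gene, and how the authors chose the cells is not given in the sources used here. A deposited metadata table holds other, non-numeric content, a text label that gives the library of each barcode. The table was checked to hold 20995 cells, 47729 lines of genes, 684313993 UMIs and 0 non-integer or negative values, and every barcode had a library. Symbols on several lines (126, with 0.039% of the UMIs) were summed, which left 47593 symbols. No cell was removed in the main analysis. Libraries held 5211, 5571, 4411, 3388 and 2414 cells in the order above, so that the first 2 exceeded the 5000 cells of the labels. Total counts were 138384240, 150984642, 146245517, 135970165 and 112729429 UMIs. The 100 most abundant genes took 39.6%, 43.4%, 42.0%, 46.1% and 48.7% of them. Doublets were called with the Scrublet method of scanpy; it marked 19 cells (0.09%), far below what such cell numbers give, so the caller has not worked here and doublets were left in.

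Counts were summed over the cells of a library and scaled to the library total and given as CPM. For each pair of libraries, genes at 10 CPM or more in either were compared by the log2 ratio after adding 5 CPM to each, and a gene counted as higher or lower from 2-fold on. With no replicate, no test across conditions was made. Intervals are exact 95% intervals for counting error alone: Poisson for CPM, conditional binomial for ratios of CPM, and Clopper-Pearson for shares of cells. Fold values are plain ratios of CPM, so they need not follow the order of the log2 ratios, which damp low values. At 10 CPM the smallest library holds 1127 UMIs of a gene. The comparisons were each starved library against the control, the amino acid against the glucose library at 6 h, and the later against the earlier time of each starvation.

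Before the data were examined, 36 pathway lists, 15 cell type marker lists and 20 single genes were fixed, together with the rule for the genes named. The rule took the 8 genes with the largest log2 ratio in each direction of each comparison (5 for a pair of times), the 20 single genes, and the 4 members of each list furthest from 0. Some genes that the rule names are not reported here. For each list with 5 or more measured members, the median log2 ratio was ranked among those of 10000 random lists of equal size matched on mean expression in 20 bins. A list was said to lie above or below its random lists when it was past the 97.5th or under the 2.5th percentile; with no replicates this ranks genes within a pair of libraries and is not a test of the condition. List members counted as higher or lower from 1.5-fold on. Lists could share genes, such as Ddit4 and Ndrg1 (ATF4 target and hypoxia lists), Slc38a2 (ATF4 target and transporter lists) and Cth (ATF4 target and serine lists). Data were also simulated as Poisson counts from the control, with 200 genes given a difference. Of genes set 3-fold apart 100% were called, of those set 1.5-fold apart 0%, and no unaltered gene was called. For lists, independent normal noise was added to the log2 ratio of each gene. Then 4.67% and 4.33% of unaltered lists and 100% of lists shifted by 0.5 passed the limits. At this depth the gene calls were fixed in advance. Neither part covers variation between libraries or list members that vary together.

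For values per cell, each cell was thinned at random to 10000 UMIs, which left out 212, 113, 55, 3 and 12 cells. S and G2/M scores were computed with scanpy, and a cell was called in the phase of its higher score when that was above 0. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 with seed 0, and were used only to look for other cell types. Gene positions are those of GENCODE M21 on GRCm38, where 7246 of 7464 expressed symbols were found. Alternatives tried were TMM factors (edgeR calcNormFactors; 1.12, 0.912, 0.960, 0.925 and 1.10), totals without mitochondrial-genome and ribosomal protein genes, no minimum or 50 CPM, 1 CPM added, a 1.5-fold limit, the mean over cells, the middle 80% of cells by UMIs, G1 phase cells, unthinned scores, a score limit of 0.1 and, added later, only cells of 15000 UMIs or more with 5% mitochondrial UMIs or less. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.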

Results

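Mouse embryonic fibroblasts, connective-tissue cells grown from mouse embryos, were profiled by single-cell RNA sequencing, in which each transcript molecule of a cell is counted through a unique molecular identifier (UMI). The wild-type cells were taken before starvation (control, 0 h), after 3 h and 6 h in medium without amino acids, and after 6 h and 12 h in medium without glucose. Each of the 5 conditions was 1 library, so no spread between replicates exists and no test across conditions was made. Values below describe these libraries, and their intervals cover counting error only. The control library differed from the starved ones in more than the nutrient. The starved cells were washed, given new medium with dialyzed serum and frozen in dialyzed serum. The control cells were kept and frozen in complete serum.

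The table held 5211 cells of the control, 5571 and 4411 cells of the 3 h and 6 h amino acid starvation, and 3388 and 2414 cells of the 6 h and 12 h glucose starvation. The labels state that 5000 cells of each sample were used. Total counts were 138384240, 150984642, 146245517, 135970165 and 112729429 UMIs in the same order. The median cell held 26112, 25959, 31218, 37459 and 44133 UMIs. At this depth the exact 95% Poisson interval of every named gene at 10 CPM (counts scaled to the library total) or more was within 5.8% of its value to either side. The median mitochondrial share of a cell's UMIs was 1.67% in the control, 1.19% and 0.995% in the amino acid libraries, and 1.31% and 1.32% in the glucose libraries. All libraries expressed the fibroblast genes Vim (691 CPM in the control), Sparc (857 CPM), Col1a1 (312 CPM), Col1a2 and Fn1, and the other 5 of the 10 fibroblast markers stayed under 10 CPM. No marker of macrophages, red blood cells, glia, adipocytes or pluripotent cells reached 10 CPM in any library. Of the other cell type markers, the smooth muscle genes Tagln and Acta2 reached 625 and 195 CPM, Stmn2 reached 97.1 CPM, Spp1 118 CPM, Msln 58.7 CPM, Runx2 44.2 CPM, Krt19 42.4 CPM, Tubb3 40.3 CPM, Sox9 29.6 CPM, Mcam 23.9 CPM, Egfl7 20.7 CPM and Tnnt2 14.9 CPM in the library where each was highest. Clustering gave 9 groups of cells, and 99.3%, 98.5%, 94.6%, 97.4% and 85.7% of the cells of the 5 libraries fell in a cluster of their own. The 4 other clusters were small. They held 283 cells with p53 targets among their top genes (89.4% from the 12 h glucose library), 216 cells of all libraries with a median of only 10351 UMIs and Tagln and Acta2 among their top genes, 106 cells of the 6 h amino acid library with a median mitochondrial share of 0.040%, and 33 cells with one of 9.51%. No cluster was named as a cell type, and genes were compared on counts summed over all cells of a library.

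**Figure D1:**
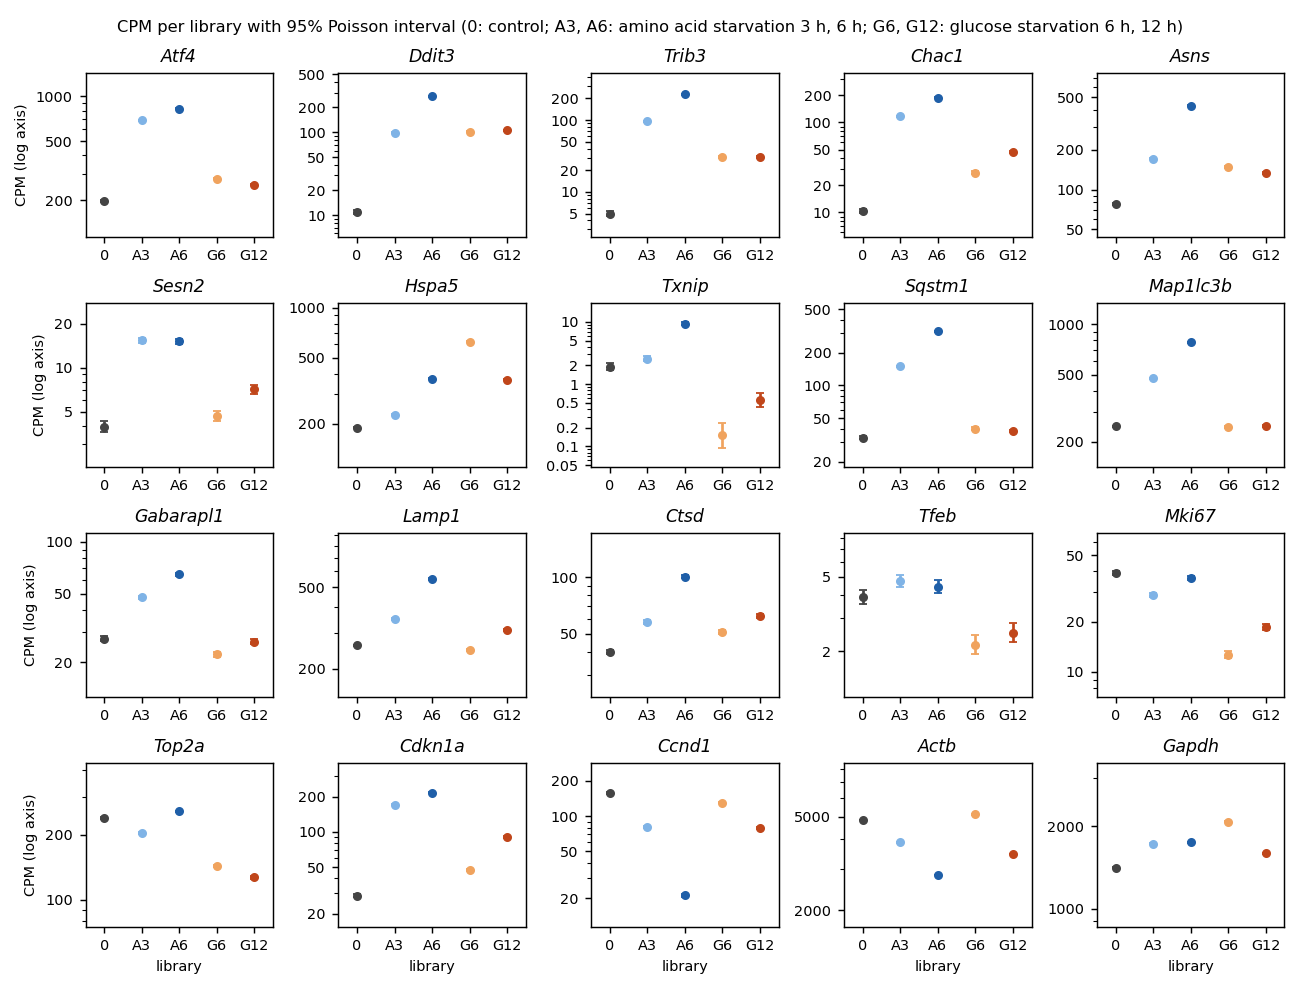
CPM of the 20 genes chosen in advance in each library on log axes, with exact 95% Poisson intervals as bars that are often smaller than the points; library names on the horizontal axis are 0 for the control, A for amino acid and G for glucose starvation, followed by the hours. Trib3 reached 228 CPM at 6 h without amino acids and 30.7 CPM at 6 h without glucose, against 4.98 CPM in the control, and Sqstm1 and Map1lc3b were high in the amino acid libraries while staying near the control in the glucose libraries.

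The 3 h amino acid library was compared with the control to ask which genes differ early in this starvation. Genes of the integrated stress response, which the transcription factor ATF4 drives when translation is curbed, were higher. All 20 measured members of the list were at least 1.5-fold higher, with a median log2 ratio of 1.81. Trib3, a pseudokinase induced by ATF4 (GRCm38 chromosome 2, 152337422 to 152344032), was 19.3-fold (95% interval 17.9 to 20.8) higher, from 4.98 to 96.0 CPM. Nupr1 was 9.40-fold higher (68.9 to 647 CPM), Chac1, an enzyme that degrades glutathione, 11.2-fold, Ddit3, which encodes CHOP, 9.08-fold, and Atf3 13.2-fold. Gadd45a (9.81-fold) and the ER-associated degradation gene Herpud1 (8.80-fold) were also among the 8 highest genes. Atf4 itself was at 691 CPM against 197 CPM. Amino acid transporters stood apart in the same direction (8 of 11 at least 1.5-fold higher, median 1.22). They were led by the cystine carrier Slc7a11 (1.42 to 45.1 CPM), Slc7a1, Slc6a9 and Slc38a2 (90.7 to 282 CPM).

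Immediate early genes, which cells also induce while being detached, were higher at 3 h without amino acids in 13 of 18 members (median 0.94), among them Egr1 (24.2 to 164 CPM), Junb (50.1 to 287 CPM) and Ier2 (70.4 to 348 CPM). FOXO targets (6 of 11, median 0.62, led by Gadd45a and Ccng2) also had a median above those of matched random lists, as had serine and one-carbon enzymes (median 0.42, led by Mthfd2 and Psph) and translation factors (median 0.31, led by Eef1a1 at 2918 to 6795 CPM). The same held for lysosome genes (median 0.30, led by Fnip1 and Flcn) and tRNA synthetases (0.20). Hypoxia targets had a median of 0.22, led by Ddit4, Ndrg1 and Vegfa. Ddit4 and Ndrg1 are also in the ATF4 list, here and wherever they lead the hypoxia list below. The hypoxia list as a whole summed to 755 CPM in the control and 680.1 CPM at 3 h. Smaller medians above random lists were those of cytosolic ribosomal proteins (0.19), YAP and TGF-beta targets (0.19, led by Skil and Smad7), core autophagy genes (0.18) and S phase genes (0.10). Lists below their random lists were the mitochondrial genome (7 of 9 genes at least 1.5-fold lower, median -0.70), nuclear genes of oxidative phosphorylation (-0.28, led by Atp5k) and cholesterol synthesis (-0.34). The lowest genes were Mrpl41, a protein of the mitochondrial ribosome (3.90-fold lower, 95% interval 3.77 to 4.04), Chst12 (6.43-fold lower), Gas1 (6.64-fold) and Sdhaf1 (4.36-fold). With them came Zfp637 (3.37-fold), the lipid desaturase Scd2 (2.65-fold, 178 to 67.1 CPM), mt-Nd6 (3.86-fold) and Them6 (3.90-fold).

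Of 6931 genes at 10 CPM or more, 156 were at least 2-fold higher and 62 at least 2-fold lower after 3 h without amino acids. From 1.5-fold on, 448 were higher and 641 lower, so the balance depends on the limit. The median gene had a log2 ratio of -0.14, and relative to that median the 2-fold counts were 215 higher and 26 lower. TMM scaling moved the median to 0.13 and the counts to 294 higher and 11 lower, and turned the median of the oxidative phosphorylation list to 0.02, still below its random lists. Cholesterol synthesis lay within random lists with 1 CPM added, with the mean over cells and in G1 cells, YAP and TGF-beta targets at 50 CPM and in G1 cells, and tRNA synthetases, core autophagy, hypoxia targets and S phase genes in G1 cells.

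After 6 h without amino acids the same stress response was larger. All 25 measured genes of the ATF4 list were at least 1.5-fold higher than in the control, with a median of 2.34. A member counts as measured at 10 CPM or more in either library. Some, such as Trib3 (4.98 CPM in the control), thus enter only through their starved level, here and at 3 h, which favours higher members. Trib3 was 45.8-fold (95% interval 42.5 to 49.4) higher, Ddit3 24.8-fold (95% interval 23.5 to 26.1) and Nupr1 18.7-fold (68.9 to 1287 CPM). Gadd45a was 18.2-fold higher, Chac1 17.9-fold, Slc7a11 46.6-fold, Atf5 13.7-fold and the snoRNA host transcript Snhg12 10.2-fold. Asns, which makes asparagine, was at 431 CPM against 78.3 CPM, and Sesn2, an inhibitor of mTORC1 signalling, at 15.1 against 3.94 CPM. Genes that supply and charge amino acids were higher as groups: 11 of 12 transporters, 12 of 18 serine and one-carbon enzymes (Mthfd2 117 to 574 CPM, Cth 3.66 to 32.6 CPM) and 12 of 20 tRNA synthetases (Sars 67.6 to 284 CPM, Tars 48.8 to 199.8 CPM).

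Lysosome genes of the CLEAR network, the set regulated by TFEB and TFE3, were at least 1.5-fold higher in 25 of 36 members after 6 h without amino acids (median 0.98, none 1.5-fold lower). From control to starved, Fnip1 had 12.6 to 87.3 CPM, the proton pump subunits Atp6v0d1 and Atp6v1c1 30.8 to 111 and 80.8 to 270.1 CPM, and Tmem55b 29.1 to 104 CPM. Lamp1 was at 550.3 against 260.1 CPM and Ctsd at 101 against 39.7 CPM. Tfeb itself was low in both (4.42 and 3.91 CPM). Core autophagy genes were higher in 10 of 20 members (median 0.47), including Map1lc3b (247 to 779.9 CPM), Gabarapl1 (27.5 to 65.0 CPM), Atg12 and Uvrag. Among autophagy receptors (median 0.39) Sqstm1, which encodes p62, was 9.42-fold higher, Bnip3l was higher (128 to 248 CPM), and Phb2 (519.6 to 251 CPM) and Fundc1 were lower.

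The 6 h amino acid library also had lower structural and lipid transcripts. Extracellular matrix genes were at least 1.5-fold lower in 15 of 26 members (median -0.68), with Col1a2 4.79-fold (95% interval 4.69 to 4.90) lower and Col1a1 at 312 to 121 CPM. Contractile genes were lower in 9 of 17 (median -0.61), led by calponin 2 (Cnn2), Tpm1 and Srf. Cnn2 was the lowest of all genes, 10.6-fold lower (240.3 to 22.6 CPM). Fatty acid synthesis (median -0.54, led by Scd2 at 7.35-fold lower and Elovl6) and cholesterol synthesis (-0.51, 9 of 20 at least 1.5-fold lower, with Msmo1 higher at 42.4 to 117 CPM) were below their random lists. So were the mitochondrial genome (7 of 9 lower, median -1.03) and nuclear oxidative phosphorylation genes (14 of 48, median -0.29). Cytokines (-0.74, led by Cxcl12 at 80.1 to 22.9 CPM) were too. The 6 measured interferon-stimulated genes had a median of -0.85, but all 27 genes of that list together were not lower (960.4 to 1044 CPM, and a median of 8 and 10 UMIs per thinned cell). Cyclin D1 (Ccnd1) was 7.47-fold (95% interval 7.19 to 7.76) lower and the CDK inhibitor Cdkn1a 7.58-fold higher. S phase genes were above their random lists (15 of 43 at least 1.5-fold higher, median 0.46, led by Cdc45, Rrm2 and Cdc6). The other lowest genes were Bola3 (5.40-fold lower), Pdlim2 (6.15-fold), Maged1 (6.55-fold) and Mrpl41 (5.23-fold). Immediate early genes (median 1.19, Egr1 24.2 to 217 CPM), FOXO targets (0.51), translation factors (0.39), hypoxia targets (0.28, led by Ndrg1 and Ddit4, with 755 and 769 CPM for the whole list) and ribosomal proteins (0.15) were above theirs.

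In all, 362 of 7115 genes were at least 2-fold higher and 451 at least 2-fold lower at 6 h without amino acids. Relative to the median gene (-0.09) the counts were 452 and 324, and with TMM scaling they were 554 and 232. Autophagy receptors, oxidative phosphorylation and ribosomal proteins lay within random lists at 50 CPM, and autophagy receptors, hypoxia targets and cytokines (median -0.16) in G1 cells.

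Between 3 h and 6 h without amino acids, 59 of 6678 genes were at least 2-fold higher at 6 h and 68 lower (44 and 96 with TMM scaling). The mitochondrial thioesterase Acot2 differed most among the higher ones (10.0-fold, 95% interval 9.21 to 10.9). It was followed by Atf5 (4.15-fold), Snhg17 (3.41-fold), Rpp38 and Hist3h2a, the last uncertain because histone genes share reads. Cnn2 (7.22-fold lower, 95% interval 6.97 to 7.49), the small heat shock gene Hspb1 (4.26-fold lower), Prss23, the tendon transcription factor Scx and Ccnd1 (3.82-fold) were lowest. Lists higher at 6 h than at 3 h were the ATF4 targets (17 of 25, median 0.89), lysosome genes (19 of 34, 0.71), serine and one-carbon enzymes (0.64), transporters (0.50) and tRNA synthetases (0.40). Also higher were S phase genes (0.40), fatty acid oxidation (0.35), G2/M genes (0.27) and core autophagy (0.23). Histones (0.19) were at the edge of their random lists and within them under 6 of the alternatives, TMM scaling among them. Fatty acid oxidation lay within random lists with the mean over cells and in G1 cells, core autophagy at 50 CPM and in G1 cells, and S phase genes in G1 cells, where the G2/M median turned to -0.30, below its random lists. Contractile genes (-0.63), YAP and TGF-beta targets (-0.51), cytokines (-0.50) and matrix (-0.47) were lower. The 6 measured interferon-stimulated genes had a median of -0.52, while the whole list summed to 1014 CPM at 3 h and 1044 CPM at 6 h. Smaller shifts down were those of heat shock genes (-0.36), FOXO targets (-0.27), fatty acid synthesis (-0.26), the mitochondrial genome (-0.26) and the proteasome (-0.15). Of the lower lists, heat shock genes and YAP and TGF-beta targets lay within random lists at 50 CPM, and cytokines, FOXO targets and the mitochondrial genome in G1 cells.

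**Figure D2:**
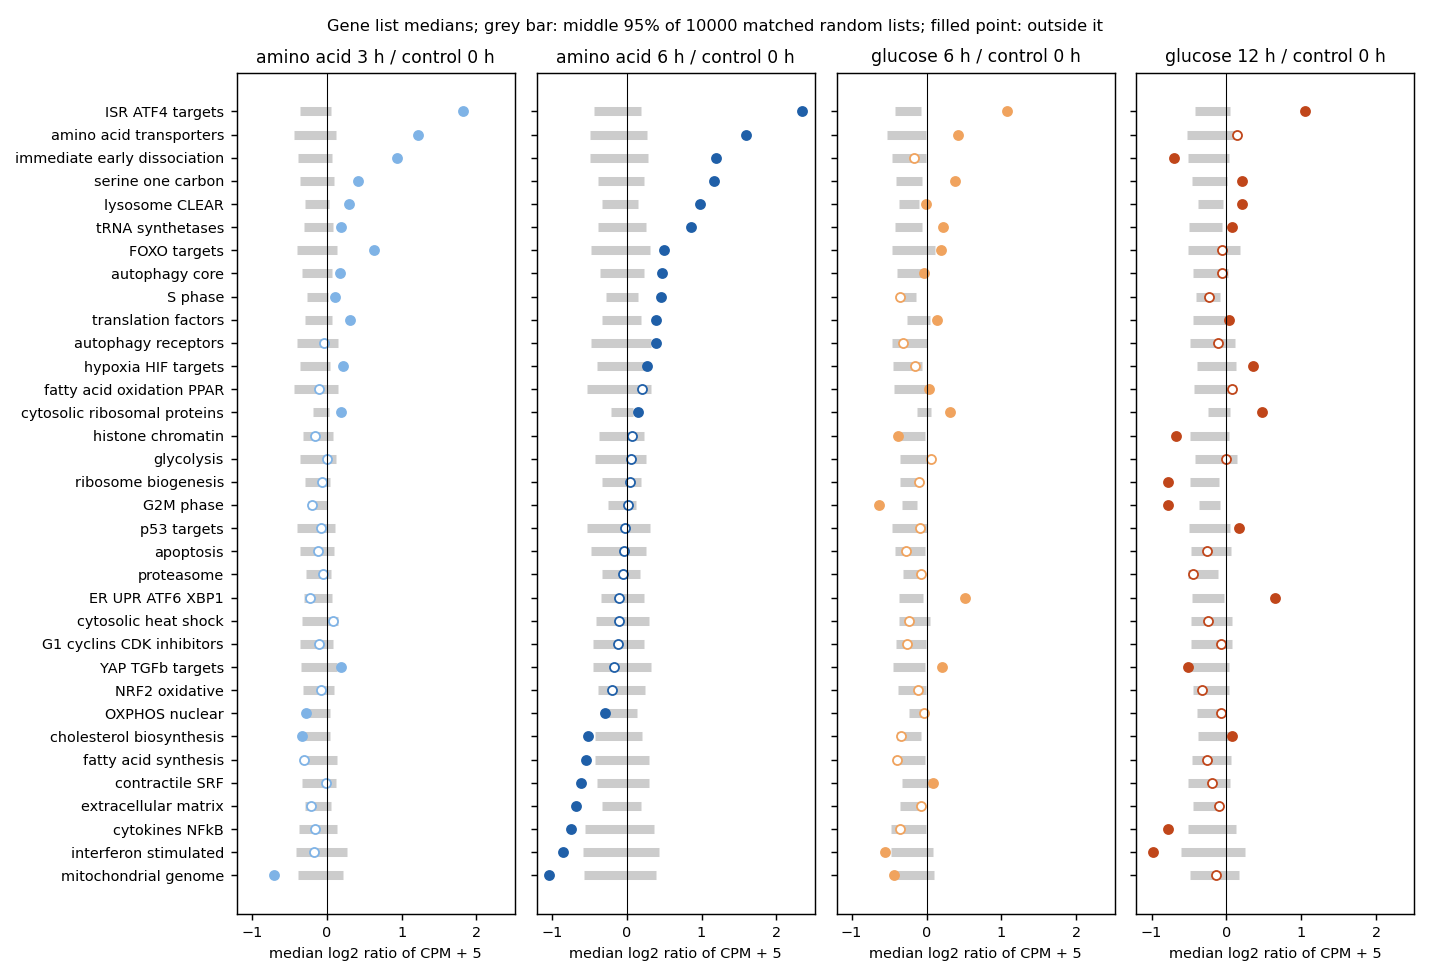
Median log2 ratio against the control of each gene list with 5 or more measured members, 1 panel per starved library; grey bars span the middle 95% of 10000 random lists of the same size matched on expression, and filled points lie outside them. The ATF4 list was to the right of its bar in all 4 panels (1.81, 2.34, 1.08 and 1.05), the lysosome list reached 0.98 only in the 6 h amino acid panel, and the ER chaperone list was filled only in the glucose panels.

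The 6 h glucose library differed from the control in fewer genes, and its stress genes were of another mix. Ddit3 was 9.28-fold (95% interval 8.80 to 9.80) higher (10.9 to 101 CPM). Genes of the unfolded protein response, which ATF6 and XBP1 induce, were at least 1.5-fold higher in 11 of 24 members (median 0.51). From control to starved, Hspa5, the chaperone BiP, had 189 to 622 CPM, Sdf2l1 36.6 to 129 CPM, Manf 285 to 768 CPM and Herpud1 17.5 to 69.4 CPM. At 6 h without amino acids Hspa5 was also higher than in the control (372 CPM), while Sdf2l1 was lower (22.8 CPM). The ATF4 list was higher in 13 of 19 members (median 1.08). Trib3 was 6.17-fold and the mitochondrial gluconeogenic enzyme Pck2 4.17-fold higher, and Atf4 at 279 CPM. The BMP antagonist Grem1 (1.80 to 23.5 CPM) and the connexin gene Gjb2 (0.412 to 12.5 CPM) were also among the highest genes. Txnip, which glucose induces through MondoA, was 12.4-fold (95% interval 7.98 to 20.4) lower but near the floor (1.92 to 0.154 CPM). The 2 genes of that list at 10 CPM or more, Klf10 and Mlx, had log2 ratios of 0.40 and 0.04.

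Proliferation genes were lower after 6 h without glucose, where 32 of 52 G2/M genes were at least 1.5-fold lower (median -0.63), among them Cenpa (442 to 157 CPM), Mki67 (38.9 to 12.7 CPM), Aurka and Cks2. Histone genes were lower in 8 of 20 (median -0.38), with the linker histone H1f0 5.14-fold (95% interval 5.01 to 5.27) lower and, uncertain because histone genes share reads, Hist1h2ap 5.76-fold and Hist1h1c 5.16-fold lower. S phase genes had a median of -0.36, just inside the range of random lists. The chemokines Ccl2 (4.95-fold lower, 161 to 32.5 CPM) and Cxcl1 (4.22-fold), the mitochondrial transcripts mt-Nd6 (11.6-fold) and mt-Rnr2 (3.73-fold), and Socs2 (3.64-fold) were the other lowest genes. YAP and TGF-beta targets (median 0.21, Ctgf 79.1 to 257 CPM) and contractile genes (0.08, with the smooth muscle markers Acta2 at 92.0 to 195 CPM and Tagln at 293 to 592 CPM) were above random lists. So were amino acid transporters (0.42), serine and one-carbon enzymes (0.38), ribosomal proteins (0.31), tRNA synthetases (0.22), FOXO targets (0.19), translation factors (0.15) and fatty acid oxidation (0.04). Interferon-stimulated genes (-0.55, led by Cxcl10) and the mitochondrial genome (-0.44) were below. All genes of the interferon list together moved little, with a median of 7 UMIs per thinned cell against 8 in the control. Lysosome (-0.00) and core autophagy genes (-0.04) lay above their random lists, whose own medians were lower, and none of them was 1.5-fold higher. Their medians turned to 0.23 and 0.19 with TMM scaling and to 0.11 and 0.07 with totals that leave out mitochondrial and ribosomal protein genes, and under both the autophagy list lay within its random lists.

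After 6 h without glucose 53 of 6854 genes were at least 2-fold higher and 110 lower. The median gene had a log2 ratio of -0.23, and relative to it 118 genes were higher and 33 lower, against 117 and 34 with TMM, and 79 and 63 with totals that leave out mitochondrial and ribosomal protein genes. Histones lay within random lists with those totals and at 50 CPM, lysosome and core autophagy genes at 50 CPM and in G1 cells, the mitochondrial genome with 1 CPM added, and G2/M genes, FOXO targets and fatty acid oxidation in G1 cells.

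At 12 h without glucose, cell division and ribosome-making genes were low while ribosomal protein transcripts were high. G2/M genes were at least 1.5-fold lower than in the control in 34 of 52 members (median -0.78), with Cenpa (3.89-fold lower, 95% interval 3.82 to 3.97), Cdc20 (4.28-fold), Cks2 (3.80-fold) and the ubiquitin-conjugating enzyme Ube2s (4.33-fold) among the 8 lowest genes. Ribosome biogenesis genes were lower in 20 of 29 (median -0.78), including Nop58 (254 to 82.7 CPM), Dkc1, Rrs1 and Myc (39.9 to 14.2 CPM). Transcripts of ribosomal proteins were on the other side (26 of 84 at least 1.5-fold higher, 1 lower, median 0.47), led by Rpl3 (1607 to 4684 CPM), and took a median of 39.7% of a cell's UMIs against 29.5% in the control. Translation factors went both ways (7 of 29 at least 1.5-fold higher and 7 lower), with Eef1a1 at 2918 to 8348 CPM, Eef2 at 687 to 1768 CPM and Eif4e at 252 to 95.7 CPM. Among stress genes, Ddit3 was 9.70-fold (95% interval 9.19 to 10.2) higher, Pck2 5.66-fold and Trib3 6.17-fold higher. In the lists, 13 of 18 ATF4 targets (median 1.05) and 12 of 23 ER genes (median 0.65, Sdf2l1 3.69-fold, Pdia4 and Pdia6) were at least 1.5-fold higher.

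Of the highest 8 genes at 12 h without glucose, 4 were uncertain. The heat shock cognate gene Hspa8 (3.54-fold higher, 95% interval 3.51 to 3.57) and the ribosomal protein pseudogenes Rpl3-ps1 (4.49-fold) and Rpl10a-ps1 (3.59-fold) have near-identical copies that share reads, and Mir703 (5.10-fold) is a small RNA gene, a class that this assay is not made to capture. Immediate early genes (median -0.70, Fosl1 54.9 to 14.9 CPM, with Klf2 higher at 20.4 to 77.9 CPM) and cytokines (-0.78, Ccl2 5.04-fold lower) were below random lists, as were interferon-stimulated genes (-0.98, Isg15 35.1 to 7.02 CPM), histones (-0.68, Hist1h2ap 19.1-fold lower) and YAP and TGF-beta targets (-0.51, Ankrd1 159 to 63.7 CPM). The interferon list as a whole moved little, with a median of 7 UMIs per thinned cell against 8 in the control. Below the control's 10th percentile of it lay 10.6% of the cells, against 8.22% of the control's own. Hist1h2ap is uncertain here too, as histone genes share reads. The other lowest genes were mt-Rnr2 (4.65-fold lower) and the RNA helicase Ddx46 (4.53-fold). Above random lists stood hypoxia targets (0.35, led by Ddit4 and Ndrg1), serine and one-carbon enzymes (0.21), lysosome genes (0.20, 6 of 33 at least 1.5-fold higher) and p53 targets (0.17, Cdkn1a 28.4 to 90.7 CPM). The median thinned cell was not higher in hypoxia targets (7 UMIs in both libraries), lysosome genes (26 against 28 in the control) or p53 targets (5 against 7), and 21.6% of the cells lay below the control's 10th percentile of p53 targets. Medians near 0 that lay above random lists were those of cholesterol synthesis (0.08), tRNA synthetases (0.08) and translation factors (0.03). The p53 list turned to a median of -0.22 among genes at 50 CPM or more and -0.48 in G1 cells, where Cdkn1a (-0.36) and the lysosome list (-0.08) turned too.

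At 12 h without glucose 96 of 7116 genes were at least 2-fold higher and 239 lower. The median gene had a log2 ratio of -0.20, and relative to it the counts were 222 and 105. With totals that leave out mitochondrial and ribosomal protein genes they were 191 and 114. TMM scaling kept the balance, with 100 higher and 203 lower. Within random lists lay translation factors at 50 CPM and in quality-limited cells, immediate early genes and p53 targets at 50 CPM, YAP and TGF-beta targets under 4 of the alternatives, and lysosome, p53 and G2/M genes in G1 cells.

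Between 6 h and 12 h without glucose, 34 of 6776 genes were at least 2-fold higher at 12 h and 67 lower. TMM made this 8 and 146, and totals that leave out mitochondrial and ribosomal protein genes 56 and 60. The balance turned with 1 CPM added (142 higher and 101 lower) and with a 1.5-fold limit (390 and 365). Among the lowest genes at 12 h were Ctgf (4.89-fold lower, 95% interval 4.76 to 5.03), Myc (5.29-fold), F3, which encodes tissue factor, and Ankrd1 (3.99-fold). Snhg20 (2.94-fold, 95% interval 2.85 to 3.02), the mitophagy receptor Bnip3 (3.39-fold), PISD, Cacna1a and Rsrp1 were highest. Ribosome biogenesis (16 of 29, median -0.66), immediate early genes (-0.64) and YAP and TGF-beta targets (-0.62) were lower at 12 h than random lists. So were contractile genes (-0.37), the proteasome (-0.37) and cytokines (-0.36). Histones (-0.28) and G2/M genes (-0.12) were also below, but histones were within random lists under 5 of the alternatives and G2/M genes with the mean over cells and in G1 cells. Cholesterol synthesis (0.45), the mitochondrial genome (0.32), lysosome genes (0.24), S phase genes (0.13) and ribosomal proteins (0.13) were higher, although TMM scaling turned the last 2 medians to -0.07 and -0.12. Lysosome genes lay within random lists at 50 CPM, and S phase genes with the mean over cells and in G1 cells. The median thinned cell hardly differed between 6 h and 12 h in the mitochondrial genome (129 and 130 UMIs) or lysosome genes (25 and 26 UMIs).

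Which nutrient was missing was compared at the shared time of 6 h, where serum and medium change were alike per the labels. Immediate early and stress transcription factors were higher without amino acids. Egr1 (chromosome 18, 34859823 to 34864984) was 24.9-fold (95% interval 23.5 to 26.4) higher, Atf5 13.2-fold, Maff 12.4-fold, Ier2 8.40-fold and Nupr1 7.88-fold. Slc7a11 (19.3-fold) and the snoRNA hosts Snhg1 (8.61-fold) and Snhg12 (8.62-fold) were next to them. The ATF4 list (21 of 25 at least 1.5-fold higher, median 1.57), transporters (1.25) and lysosome genes (23 of 35, 0.93) were higher without amino acids. So were core autophagy (0.50), autophagy receptors (0.67, Sqstm1 40.1 to 313 CPM), serine and one-carbon enzymes (0.82) and tRNA synthetases (0.64). The same side held S phase (30 of 43, 0.85) and G2/M genes (30 of 52, 0.64, Aurka 22.3 to 114 CPM), immediate early genes (0.68), FOXO targets (0.63) and hypoxia targets (0.62). Values in this paragraph run from the glucose to the amino acid library.

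Lower without amino acids than without glucose at 6 h were ER chaperones (14 of 24 at least 1.5-fold lower, median -0.66, Sdf2l1 5.66-fold lower, 95% interval 5.45 to 5.87, with Herpud1 higher at 69.4 to 204 CPM). Contractile genes (11 of 17, -0.86, Cnn2 14.6-fold lower, 95% interval 14.1 to 15.1) and matrix genes (-0.59) were lower as well. The mitochondrial genome (-0.60), YAP and TGF-beta targets (-0.39) and nuclear oxidative phosphorylation genes (-0.25) were lower too. Ccnd1 was 6.17-fold lower, Hspb1 5.84-fold, Cdc42ep3 5.48-fold, Tgfb1i1 7.54-fold and Ctgf 5.21-fold. In all, 670 of 6829 genes were at least 2-fold higher without amino acids and 268 lower; relative to the median gene (0.13) the counts were 464 and 376. Core autophagy, autophagy receptors and immediate early genes lay within random lists at 50 CPM, and tRNA synthetases, hypoxia targets, the mitochondrial genome and matrix genes in G1 cells, where the G2/M median turned to -0.35, below its random lists.

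Some lists stayed within their random lists in all 4 comparisons with the control. At 3 h and 6 h without amino acids and 6 h and 12 h without glucose, the medians were those of glycolysis (0.00, 0.06, 0.05, 0.00), the proteasome (-0.04, -0.05, -0.08, -0.44), heat shock genes (0.09, -0.11, -0.23, -0.25), and NRF2 targets (-0.07, -0.19, -0.11, -0.32). The same held for G1 cyclins and CDK inhibitors (-0.11, -0.11, -0.27, -0.08) and apoptosis genes (-0.11, -0.03, -0.27, -0.27). A median within random lists did not mean a level list. At 6 h without amino acids all apoptosis genes together had 1219 to 2079 CPM from control to starved. Above the control's 90th percentile lay 61.8% of the cells. The G1 list had 2651 to 3657 CPM, with 46.9% of cells above that percentile. Most of its rise lay in the snoRNA host Gas5, a member of the list (759 to 1691 CPM). Of the cyclins and inhibitors in it, Cdkn1a was higher (28.4 to 216 CPM) and Ccnd1 lower (158 to 21.1 CPM). NRF2 targets had 46.5% of cells below the control's 10th percentile there (12216 to 9649 CPM), and the proteasome 51.3% at 12 h without glucose (8333 to 6292 CPM). Metallothioneins had too few measured members to rank (Mt1 282 CPM in the control, 856 CPM at 6 h without amino acids and 566 CPM at 12 h without glucose). The reference genes Actb and Gapdh were not level either. In the control and then in that order, Actb had 4839, 3887, 2823, 5111 and 3464 CPM and Gapdh 1409, 1728, 1747, 2080.2 and 1594 CPM.

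The genes that differed from the control were in part the same for both starvations at 6 h. Among 6765 genes compared in both, 283 were at least 2-fold higher without amino acids and 49 without glucose, and 24 were higher in both, where independent lists would share 2.05. Of the genes at least 2-fold lower, 19 were shared against 7.33 for independent lists, and 5 genes went in opposite directions. Part of the excess may come from the shared control library. Both starved libraries also shared the wash, new medium and dialyzed serum, which cannot be told apart from starvation here. Counting noise alone gave 0 shared genes in 20 simulations, which the depth fixes in advance and which says nothing on variation between libraries.

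**Figure D3:**
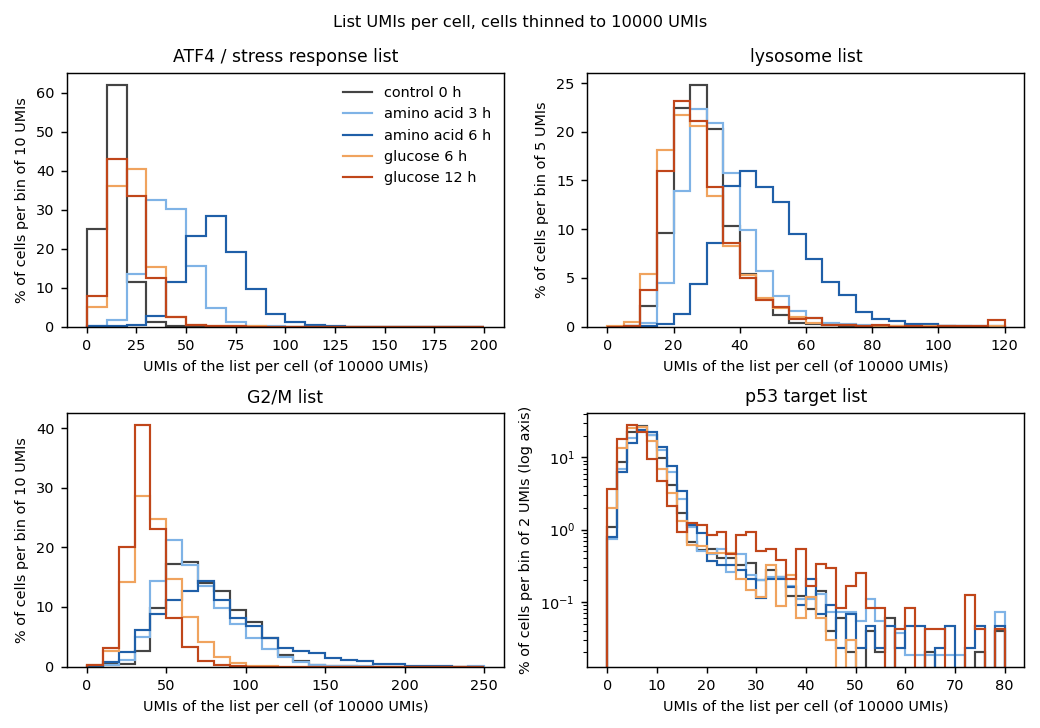
Histograms over cells of the UMIs of 4 gene lists per cell, each cell thinned to 10000 UMIs, as the percentage of a library's cells per bin; the last bin holds higher values too, and the p53 panel has a log axis. The ATF4 list distribution of the 6 h amino acid library (median 64 UMIs) barely overlaps that of the control (median 13), the G2/M distributions of the glucose libraries lie to the left, and the p53 panel has a long right tail in every library.

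Single cells were examined to ask whether these differences ran through whole libraries. With every cell thinned to 10000 UMIs, the ATF4 list had a median of 13 UMIs per cell in the control, 40 and 64 after 3 h and 6 h without amino acids, and 21 and 19 after 6 h and 12 h without glucose (12.7, 40.4, 63.9, 21.5 and 19.5 per 10000 UMIs without thinning). Above the control's 90th percentile lay 97.1% and 99.7% of the cells of the amino acid libraries and 49.2% and 41.0% of those of the glucose libraries. For lysosome genes the share above that percentile was 68.1% at 6 h without amino acids, against 19.9% at 3 h, 10.7% at 6 h without glucose and 11.7% at 12 h. Below the control's 10th percentile of G2/M genes lay 64.4% and 82.3% of the cells at 6 h and 12 h without glucose, against 15.7% and 15.5% in the amino acid libraries. Thinning left out 212, 113, 55, 3 and 12 cells with fewer UMIs.

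Cell cycle phase calls from S and G2/M scores of thinned cells put 97.6% of control cells (95% exact binomial interval 97.1 to 98.0) in S or G2/M. The share was 98.6% (98.2 to 98.9) in each amino acid library, 71.5% (69.9 to 73.0) at 6 h without glucose and 66.2% (64.3 to 68.1) at 12 h. S phase calls were 14.3% in the control, 31.9% and 45.4% at 3 h and 6 h without amino acids, and 9.96% and 18.6% at 6 h and 12 h without glucose. The level of these shares depends on the score limit, since 25.1%, 18.8%, 6.93%, 69.0% and 82.0% of the cells lay within 0.1 of it, and the calls alone do not show that cells were dividing. Free RNA in the droplets also enters such scores and was not measured here. At the level of genes, Mki67 had 38.9, 28.9, 36.6, 12.7 and 18.5 CPM in the 5 libraries and Top2a 240.1, 203, 256, 143 and 127 CPM.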

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

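Contractile genes and 5 single genes were on opposite sides of the control in the 6 h libraries of the 2 starvations. The contractile list, targets of SRF, had a median log2 ratio of -0.61 without amino acids and 0.08 without glucose. The growth-response factor Egr1 had 2.93 and -1.09. The genes Chic2 (1.0 and -1.06), Depdc1a, a mitotic gene (1.08 and -1.11), Luc7l3, a splicing factor (1.21 and -1.20), and Mgea5, which encodes O-GlcNAcase, the enzyme that removes a sugar made from glucose off proteins (1.41 and -1.07), followed the same split. The 5 genes, of which only Egr1 fell under the rule for named genes, were picked out after their values were seen. All were noted because the 2 starvations gave opposite signs, each past its limit. The difference was not tested, since each value rests on 1 library.

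Targets of YAP and TGF-beta, among them Ctgf and Ankrd1, were on opposite sides of the control at the 2 times of glucose starvation, with a median of 0.21 at 6 h and -0.51 at 12 h. They were noted for the opposite signs at the 2 times. This difference was not tested either, and the value at 12 h lay within its random lists with 1 CPM added, with the mean over cells, among genes at 50 CPM or more and in G1 phase cells.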

How the results depend on the processing

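The quality-limited cells (15000 UMIs or more, 5% mitochondrial or less, no called doublet) were an alternative chosen after the data were seen. Counts of genes are given as higher/lower, in the order amino acids 3 h, amino acids 6 h, glucose 6 h, glucose 12 h against control, then 6 h amino acids against glucose, then the later against the earlier time of amino acids and of glucose. All 14 counts stayed within 1.5 times under quality-limited cells, the mean over cells, the middle 80% of cells and no CPM minimum. TMM scaling gave 294/11, 554/232 and 117/34 for the first 3 and 8/146 for the glucose times. Totals without mitochondrial and ribosomal protein genes gave 41 lower, 63 lower, 191/114 and 56 higher for amino acids 3 h, glucose 6 h, glucose 12 h and the glucose times. A minimum of 50 CPM, which compares fewer genes, gave 92/29, 229/238, 32/46, 389/135 for the nutrients, 36/37 for the amino acid times and 9 higher for the glucose times. Adding 1 CPM let genes near the floor pass: 155, 699 and 232 lower for the first 3, then 190/372, 113/139 and 142/101 for glucose 12 h and the pairs of times. The looser 1.5-fold limit gave 448/641, 929/1378, 206/889, 418/1263, 1691/810, 446/410 and 390/365. G1 cells alone (121, 77, 61, 966 and 812 cells) gave 163 lower for amino acids 3 h and 104/157 for the amino acid times, where few cells are left.

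Shares of cells in S or G2/M were 98.7% (control), 99% (amino acids 3 h), 80.6% (glucose 6 h) and 78.7% (glucose 12 h) without thinning, and 74.6%, 81.0%, 92.9%, 28.4% and 16.4% with a score limit of 0.1. Of 238 list medians, 122 lay outside their random lists. There stayed 117 with 1 CPM added, 120 with TMM, 118 without mitochondrial and ribosomal protein genes, 119 in quality-limited cells, 117 with the mean over cells, 88 in G1 cells, where 2 G2/M medians lay outside on the other side, and 76 of those with enough genes at 50 CPM. Signs turned with TMM for oxidative phosphorylation at amino acids 3 h (0.016), for S phase (-0.069) and ribosomal protein genes (-0.12) between the glucose times, and for core autophagy (0.19) and lysosome genes (0.23) at glucose 6 h, the last pair also without mitochondrial and ribosomal protein genes (0.073 and 0.11). The p53 list at glucose 12 h turned at 50 CPM (-0.22) and in G1 cells (-0.48). In G1 cells alone these turned too: S phase at amino acids 3 h (-0.035), FOXO targets at glucose 6 h (-0.10), lysosome genes at glucose 12 h (-0.079), G2/M genes between nutrients (-0.35), between amino acid times (-0.30) and between glucose times (0.087), and histones between amino acid times (-0.010). So did Txnip at amino acids 6 h (-0.12) and between amino acid times (-0.20), Cdkn1a at glucose 6 h (-0.67) and 12 h (-0.36), Ctsd at glucose 12 h (-0.13) and Top2a between nutrients (-1.51). Choosing G1 cells removes cells by their S and G2/M genes. It also kept cells with 20 or more UMIs of the p53 list unevenly. In the control 17.8% of these cells and 1.87% of the others were called G1. The shares were 11.7% and 1.01% at 3 h and 10.9% and 1.09% at 6 h without amino acids. They were 41.7% and 28.2% at 6 h without glucose, and 34.4% and 33.8% at 12 h. Relative to the other cells, the G1 choice thus favoured these cells more in the control and amino acid libraries than in the glucose libraries. Whether this accounts for the turned signs of Cdkn1a and the p53 list in G1 cells was not tested. For the other shifts the cause was not tested either.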

Other observations

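Tests chosen after the result was seen were those of TOP mRNAs as a class, of more nuclear RNA per cell, and all 3 on the p53 subset, as were the snoRNA host list and the p53 subset's limit. In every library a few cells carried high p53 target transcripts. Cells with at least 20 UMIs of the p53 list among 10000 made up 3.48% of the control (95% exact binomial interval 2.99 to 4.03), 3.76% and 3.17% at 3 h and 6 h without amino acids, 2.84% at 6 h without glucose and 7.99% (6.94 to 9.15) at 12 h without glucose. Members of the list are high in these cells by selection. Genes outside it, chosen after their values were seen, were high with them: in the 12 h glucose library Dcxr, which reduces sugars, was at 145 CPM in these cells and 7.12 CPM in the others, and the spindle gene Psrc1 at 69.2 and 4.73 CPM. In the control they were at 95.7 and 4.52 CPM and at 49.7 and 4.90 CPM. Whether Dcxr and Psrc1 themselves respond to p53 was not tested. The limit lies on a tail, with 107, 141, 120, 73 and 100 cells between 16 and 23 UMIs, and at 15 UMIs the shares were 5.46%, 6.41%, 6.63%, 4.49% and 10.9%, at 25 UMIs 2.44%, 2.62%, 2.27%, 1.77% and 6.04%.

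Host transcripts of small nucleolar RNAs, spliced RNAs whose introns hold those RNAs, were highest at 6 h without amino acids. The 11 measured hosts, grouped after Snhg12 and Snhg1 had been seen among the largest differences, had a median log2 ratio to the control of 1.03 at 6 h and 0.32 at 3 h without amino acids, and 0.00 and 0.31 at 6 h and 12 h without glucose. At 6 h without amino acids 6 of them were at least 2-fold higher. The medians at 3 h without amino acids and 12 h without glucose were alike, and both lay above random lists (percentiles 99.88 and 99.91).

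Ribosomal protein transcripts were high at 12 h without glucose (median 0.47 for 84 genes), and deeper cells do not account for it: among cells of 25000 to 35000 UMIs the median share differed by 10.6 percentage points (40.3% of 422 cells against 29.7% of 2031), and by 10.2 over all cells. Short transcripts as such do not either, as 79 other genes matched on length had a median of -0.22, although their expression was lower (mean CPM 980.5 against 3674). TOP mRNAs that encode no ribosomal protein, 20 genes with the 5' motif that mTORC1 acts on, had a median of 0.60, at the 100th percentile of matched random lists. Of these, 17 had a log2 ratio above 0 but only 10 were at least 1.5-fold higher, and Hnrnpa1 (-0.38) and Nap1l1 (-0.40) were lower. Many, such as Eef1a1 and Eef2, are also in the translation factor list seen before, so the 2 lists are not independent. The pattern may reach beyond ribosomal proteins to a part of the TOP mRNAs. The same genes had medians of 0.49 and 0.30 at 3 h and 6 h without amino acids and 0.48 at 6 h without glucose, all above random lists, so it is not special to 12 h without glucose. All starved libraries differ from the control in serum, and starvation and serum stay inseparable here.

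For the snoRNA hosts, more nuclear RNA per cell was argued against by nuclear-retained RNAs, whose median was 0.12 over 5 genes. Weaker nonsense-mediated decay, which degrades many of these hosts, was examined through decay factors whose own transcripts it targets. Their median of -0.11 over 7 genes was at percentile 45.6 of random lists, so they were not raised as a set. This cannot decide the question, since transcript levels of 7 factors are an indirect readout and decay itself was not measured. Apart from this decay no biological explanation was tested.

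For the p53 subset at 12 h without glucose, damaged cells were argued against by a mitochondrial share of 0.868 times that of the other cells. Doublets were argued against by a UMI total of 0.875 times, and a quite different cell type by only 8 of 2301 genes outside the list differing 4-fold or more. Only genes at 50 CPM or more were counted, and a related cell type or state need not differ in many of them. The count therefore cannot exclude one. A p53 response in a part of the cells, present before starvation, remains as a hypothesis. Whether its larger share belongs to 12 h without glucose or to that library was not tested.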
